A study of Mus musculus with 20 samples.

How the data were processed

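RNA was sequenced from bone-marrow-derived macrophages of C57BL/6 mice that were wild type (WT, 10 libraries), carried a 5 bp knockout of Trem2 (KO, 5 libraries) or carried the R47H substitution in Trem2 (R47H, 5 libraries). Per the labels' protocols, marrow of mice aged 4 to 5 months was cultured for 6 days in 50 ng/ml CSF-1, and poly-A RNA was made into strand-specific libraries by the dUTP method. Reads were paired and 75 bases long, per the labels' protocols. The authors deposited one table per library with 51456 gene symbols and a column named FPKQ, treated here as an FPKM on a scale set by a quantile. The submitters' processing notes name RSEM and the mouse genome GRCm38, and their versions and settings are not given in the sources used here. In each library the 71.5th percentile over protein-coding genes lay near 10 (9.98 to 10.0), which is read here as that scale. The definition of FPKQ is not given in the sources used here. Values from RSEM can divide fragments between similar genes, so levels of paralogs such as the H2 and C1q genes are less certain.

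Coordinates came from GENCODE M21 on GRCm38, which held 45889 of the 51456 symbols (89.2%). Depth was estimated from the low values of genes with a single transcript of at least 600 bases. In each library between 83.5% and 86.6% of these values were whole multiples of one fragment, within a tolerance of 0.1 fragment. One fragment was worth 0.0278 to 0.0426 FPKQ times kb, and because the share of whole values was incomplete and effective lengths are unknown, no count test was run. Depth as a covariate means the log2 of that size, which also moves with the FPKQ scale. FPKQ 1 in a gene of 2 kb corresponded to 57.3 ± 6.30 fragments (SD, n = 20), so counting error weighs most on genes near the minimum level. Pearson correlations of log2 values between libraries within a group ran from 0.980 to 0.995 over the tested genes.

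Genes with a mean of at least 1 FPKQ over the 20 libraries were kept (10843 genes). Values were analysed as log2(FPKQ + 1), so fold changes are on that scale and understate the change of genes with low levels. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), in a single model of the 3 groups without covariates, with Benjamini-Hochberg adjustment and an adjusted p under 0.05. All adjusted p-values of genes come from limma. The exact permutation tests of Trem2 compared mean log2 values over all 3003 splits of 15 libraries or all 252 splits of 10, counting both directions. Gene lists were tested with camera from limma with a preset correlation of 0.01, adjusted over the 26 lists with tested members, and again with an estimated correlation. With the estimate, no list remained called in KO or in R47H against KO, and 2 did in R47H against wild type. The 28 lists covered cell cycle, lipid, lysosome, inflammation, antigen presentation, stress, metabolism, macrophage and Trem2 pathway genes, and markers of other cell types and of sex. Those for stroma and erythroid cells had no tested member. Summaries, depth and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

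Apart from the alternatives and tests said below to have been chosen later, the groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. For each mutant against wild type the rule took Trem2 and the 12 genes with the largest rise and the 12 with the largest fall among those called. They needed the same sign against WT Rep1 to Rep5 and WT Rep6 to Rep10 and a mean in the higher group at or above the median of all tested genes, 13.4 FPKQ. Unnamed gene models and sex-linked genes were left out, and for R47H against KO the rule took 6 each way. Up to 4 members of each list with the smallest adjusted p were also named. Markers of other cell types are named from the fixed lists, and other genes outside the rule are said to have been chosen after their values were seen.

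Alternatives covered the wild-type set, the pseudocount, the filter on low values, scaling, robust moderation, library weights, the groups in the fit, covariates, a replicate block and leaving out each library. Because both mutants were compared with the same wild-type libraries, unchanged groups were simulated 100 times against those controls, and the comparison was repeated with the controls split. The labels do not tie replicate numbers across genotypes to litters. The test was tried on simulated data with 200 of 10843 genes changed. For KO against wild type it recovered 73.1% of genes changed 1.25-fold, 89.6% of those changed 1.5-fold and 100% of those changed 2-fold, with 5 false calls. For R47H against wild type the shares were 59.7%, 89.6% and 100% with 8 false calls, and for R47H against KO 56.7%, 89.6% and 95.5% with 11 false calls. In the simulated KO comparison a shift of 0.5 on the log2 scale in the lysosome list was called, and 0 other lists were. The simulated genes varied independently, so this does not test list calls where members vary together. In the data the estimated correlation was, for example, 0.57 for G2 and M phase and 0.75 for MHC class II.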

Results

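Transcript levels were measured by strand-specific poly-A RNA-seq in macrophages grown from mouse bone marrow for 6 days with 50 ng/ml CSF-1, the growth factor that drives bone marrow cells to become macrophages. The 20 libraries comprised 10 from wild-type mice (WT Rep1 to Rep10), 5 from mice with a Trem2 knockout (KO, labelled as 5 bp) and 5 from mice with the R47H substitution knocked into Trem2 (R47H), a change whose human counterpart is associated with Alzheimer's disease. Trem2 is a lipid-sensing receptor of macrophages and microglia that signals through Tyrobp and the kinase Syk. The submitters' design text gives 5 animals per genotype, with wild-type littermates of each mutant line, but the labels do not say which wild-type libraries belong to which line. All 10 wild-type libraries therefore served as the control for both mutants, and each mutant was also compared with WT Rep1 to Rep5 and with WT Rep6 to Rep10 separately. In the order of the sample list, WT Rep1 to Rep5 come just before KO and WT Rep6 to Rep10 just before R47H. That order may reflect the litters but does not name them, and values for that matching are given beside the main ones. Most low values in the files were whole multiples of 1 fragment, and FPKQ 1 in a gene of 2 kb corresponded to at most 71.8 fragments per library. The mean was 61.7 ± 5.17 fragments in wild type (SD, n = 10), 52.4 ± 3.87 in KO (n = 5) and 53.3 ± 3.69 in R47H (n = 5), so FPKQ 1 rested on fewer fragments in the mutants. Fragments on single-transcript genes averaged 3.18e+06 in wild type, 3.21e+06 in KO and 3.02e+06 in R47H, so KO libraries did not hold fewer. No pair among the 20 libraries held identical values, and 10843 genes were tested.

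Trem2 itself (chromosome 17, 48346401 to 48354147, plus strand, GRCm38) was present at 806 ± 60.6 FPKQ in wild type (SD, n = 10), 24.1 ± 0.435 in KO (n = 5) and 652 ± 137 in R47H (n = 5). KO libraries held 2.99% of the wild-type mean, a log2 difference of -5.00 with a two-sided exact permutation p of 6.66e-04, the smallest that 3003 splits can give. The 5 KO libraries lay between 23.7 and 24.8, far below the lowest wild-type library at 690.5. R47H libraries held 80.9% of the wild-type mean, a log2 difference of -0.33 (exact permutation p = 0.0167, limma adjusted p = 0.0110). Their values were 673, 772, 794, 496 and 527 for replicates 1 to 5, so 3 of the 5 lay below the wild-type minimum. Against WT Rep1 to Rep5 alone the R47H difference was -0.39 (exact p = 0.00794), and against WT Rep6 to Rep10 alone it was -0.27 and did not pass (exact p = 0.135). Of the 8 tested genes that flank Trem2, 2 rose, 1 fell and 5 did not pass in KO, and none passed in R47H. In KO, Frs3 and Usp49 rose by 0.33 and 0.26 and Oard1 fell by 0.21. All of these calls were lost against WT Rep1 to Rep5 alone (limma adjusted p = 0.0536, 0.0972 and 0.170) and with a replicate block (adjusted p = 0.0764, 0.133 and 0.112), and that of Oard1 also without any one of WT Rep2, Rep3, Rep6, Rep8, Rep9 or Rep10 or KO Rep2, Rep4 or Rep5 (limma adjusted p up to 0.190). Adjusted over the list alone 2 rose and none fell, and the list test gave adjusted p = 0.819 for KO and 0.740 for R47H.

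**Figure D1:**
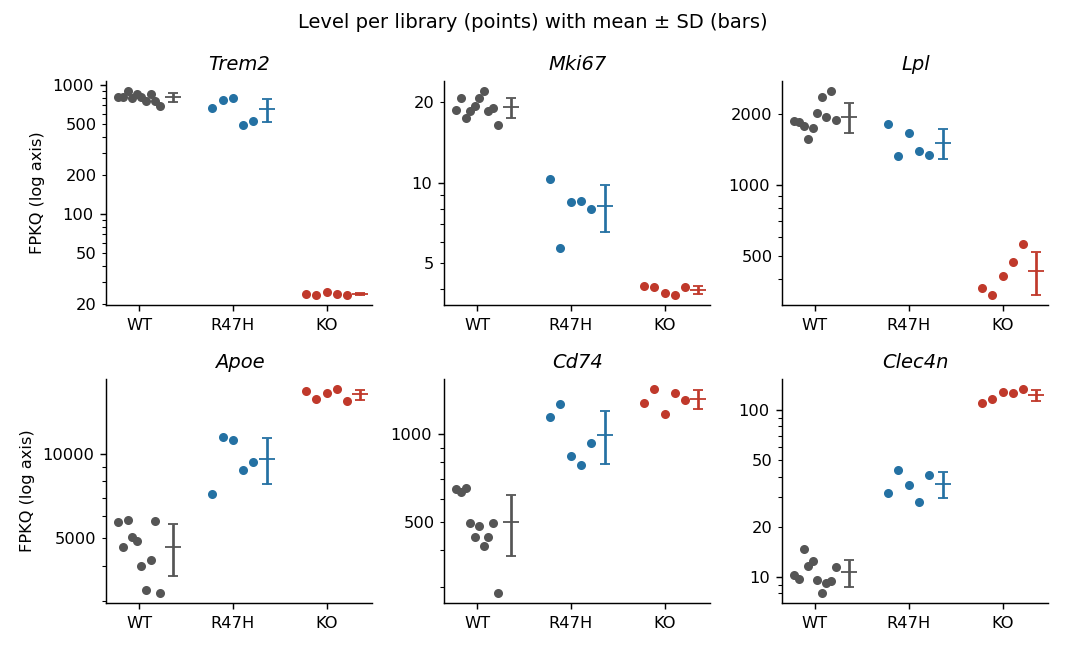
Level of 6 genes in each library, in FPKQ on a log axis, by genotype; points are libraries and bars give the mean ± SD (n = 10 WT, 5 R47H, 5 KO). In each panel the R47H mean lies between the others, as for Trem2 with 806, 652 and 24.1 FPKQ in WT, R47H and KO.

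The comparison of KO with wild type asks which transcripts depend on Trem2 in cultured macrophages. Genes of cell division were far lower in KO. Mki67, the proliferation marker, stood at 3.97 ± 0.142 FPKQ in KO (SD, n = 5) against 19.2 ± 1.64 in wild type (n = 10). Cyclin A2, encoded by Ccna2, stood at 1.75 ± 0.154 against 17.7 ± 1.76, and cyclin D1, encoded by Ccnd1 and acting in entry into the cycle, stood at 6.02 ± 1.36 against 57.8 ± 15.1. Of the 22 tested genes of the G2 and M phase list, 22 fell and none rose, with a median log2 fold change of -1.95 (camera adjusted p = 7.02e-23, adjusted p = 0.0807 with an estimated correlation). Examples are the topoisomerase Top2a (log2 fold change -2.60, SE 0.11, limma adjusted p = 3.28e-14) and the spindle motor Kif11 (-2.44). Of the 24 tested S phase genes, 23 fell and none rose, with a median of -1.20 (adjusted p = 2.20e-20, adjusted p = 0.0807 with an estimated correlation). The helicase subunits Mcm5, Mcm6 and Mcm7 fell by 2.00, 1.38 and 1.70 on the log2 scale, and Uhrf1, which maintains DNA methylation, fell by 2.42. Ube2c, Ccnb2, Pclaf, Birc5, Rrm2 and Tk1, which act in mitosis or in nucleotide and DNA synthesis, were among the 12 largest falls, at -2.87, -2.80, -2.77, -2.77, -2.73 and -2.71. The counts of both lists were the same when adjusted over the list alone.

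All 21 tested genes of cholesterol synthesis fell in KO, with a median log2 fold change of -0.92 (adjusted p = 3.24e-13, adjusted p = 0.216 with an estimated correlation), and all 21 also fell when adjusted over the list alone. The sterol demethylase Cyp51 went from 57.7 ± 10.4 FPKQ in wild type to 17.6 ± 1.77 in KO, Idi1 from 60.7 ± 11.6 to 18.4 ± 1.76, and squalene epoxidase, encoded by Sqle, changed by -1.35 on the log2 scale. Lipoprotein lipase, encoded by Lpl, fell from 1948 ± 281 to 429.9 ± 88.6, and the fatty acid desaturases Scd1 and Scd2 fell by 2.11 and 2.00 on the log2 scale. Apolipoprotein E, encoded by Apoe, rose from 4659 ± 981 to 16357 ± 676 (log2 fold change 1.84, SE 0.14, limma adjusted p = 3.61e-10). The list of LXR targets and lipid efflux genes, to which these last genes belong, had 6 members that rose, 7 that fell and 3 that did not pass, and no call as a list (adjusted p = 0.453), with the same counts adjusted over the list alone. Glycolysis and hypoxia genes fell more often than they rose, 15 against 2 of 20, with a median of -0.40 (adjusted p = 0.00202, adjusted p = 0.412 with an estimated correlation), and 15 against 3 adjusted over the list alone. Pkm, Pfkp and Pdk1 fell by 0.62, 0.51 and 0.68, while Hif1a, a transcription factor of the hypoxia response, rose by 0.79.

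The largest single rises in KO are given first, then the MHC class II and lysosome lists. Thbs1 (chromosome 2, 118111876 to 118127133, GRCm38), which encodes the matrix protein thrombospondin 1, had the largest rise, from 7.65 ± 1.84 to 129.6 ± 10.6 FPKQ (log2 fold change 3.94, SE 0.18, limma adjusted p = 1.35e-13). The C-type lectin gene Clec4n (chromosome 6, 123229843 to 123247021) rose from 10.7 ± 1.97 to 123 ± 9.52, and the inhibitory Fc receptor gene Fcgr2b from 37.9 ± 4.90 to 193 ± 5.19. The other genes among the 12 largest rises were Mmp14, F13a1, Ms4a4a, Vcam1, Cd4, Cmklr1, Slc40a1, Itgal and Ednrb, with log2 fold changes of 3.08, 3.06, 2.83, 2.60, 2.59, 2.47, 2.44, 2.09 and 2.06. They include the iron exporter Slc40a1, the adhesion molecules Vcam1 and Itgal, and Cd4, best known from helper T cells. All 7 tested MHC class II genes rose, with a median of 1.43 (adjusted p = 2.01e-04, adjusted p = 0.328 with an estimated correlation), and all 7 rose when adjusted over the list alone. The invariant chain gene Cd74 rose by 1.43 and H2-Aa from 146 ± 40.7 to 447 ± 57.3. Of 26 lysosomal genes 18 rose, 1 fell and 7 did not pass, with a median of 0.32 (adjusted p = 1.39e-04, adjusted p = 0.222 with an estimated correlation), and 19 rose when adjusted over the list alone. Prosaposin, encoded by Psap, rose from 6745 ± 252 to 12731 ± 732, and Tpp1 rose by 0.58. Under quantile normalization the log2 fold change of Psap was 0.12 and its call was lost (limma adjusted p = 0.0879). That method sets values by rank, so it cannot size a rise of a gene already near the top of the scale.

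Macrophage identity genes rose in 13 and fell in 4 of 18 cases in KO, with a median log2 fold change of 0.41 (adjusted p = 0.0193, adjusted p = 0.328 with an estimated correlation). The counts were the same adjusted over the list alone, and the call was lost under quantile normalization (adjusted p = 0.149). Mertk, a receptor for the uptake of dead cells, rose by 1.84 and the CSF-1 receptor gene Csf1r by 0.48, while Cd14, a co-receptor for lipopolysaccharide, fell by 1.26. Of 12 genes of alternative activation 8 rose and 2 fell, with a median of 0.76 (adjusted p = 0.00351, adjusted p = 0.161 with an estimated correlation), and 9 rose and 2 fell adjusted over the list alone. These included Tgm2 at 1.56, the mannose receptor gene Mrc1 at 0.95 and Mgl2 at 1.71. Immediate early and heat shock genes fell in 11 of 16 cases and 1 rose, with a median of -0.43 (adjusted p = 0.0124, adjusted p = 0.503 with an estimated correlation), and 12 fell adjusted over the list alone. That call was lost against WT Rep1 to Rep5 alone (adjusted p = 0.0652) and with a minimum mean of 5 FPKQ (adjusted p = 0.0692). Of 17 inflammatory genes 5 rose and 10 fell, with no call as a list (adjusted p = 0.228). Tnf and Ccl4 fell by 1.23 and 1.28, and Il1b rose by 1.36. Of the disease-associated microglia genes 10 rose and 7 fell of 23 (adjusted p = 0.783), with Spp1 lower at -1.50 beside the higher Apoe. Among 20 genes of Trem2 signalling 6 rose and 5 fell (adjusted p = 0.896), and Syk rose by 0.65 and the lipid phosphatase gene Inpp5d by 0.48. The counts of these last 3 lists were the same adjusted over the list alone.

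In total 5636 of 10843 genes passed in KO against wild type, 3063 higher and 2573 lower. With a change of at least 1.5-fold 1320 passed, 603 higher and 717 lower. Against WT Rep1 to Rep5 alone 4508 genes passed and against WT Rep6 to Rep10 alone 5317, and 3832 passed against both in the same direction. When libraries were rescaled to equal sums the share of higher calls moved from 54.3% to 36.1%, so the direction of small changes depends on the scale.

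The comparison of R47H with wild type asks which transcripts the substitution changes while most Trem2 mRNA remains. Of the 9 lists called in KO, 8 were called in the same direction here, each with a median nearer 0 when all 10 wild-type libraries were the control. For MHC class II this did not hold with KO against WT Rep1 to Rep5 (1.21) and R47H against WT Rep6 to Rep10 (1.23). Mki67 stood at 8.19 ± 1.65 FPKQ in R47H (SD, n = 5) against 19.2 ± 1.64 in wild type (n = 10), and Ccna2 at 6.68 ± 1.42 against 17.7 ± 1.76. All 22 tested G2 and M phase genes fell, with a median log2 fold change of -1.06 (camera adjusted p = 3.00e-37, adjusted p = 0.0121 with an estimated correlation). Of 24 S phase genes 22 fell and none rose, with a median of -0.65 (adjusted p = 9.66e-31, adjusted p = 0.0121 with an estimated correlation). Adjusted over the list alone 23 of the S phase genes fell. The 12 largest falls were Ccnb2, Ccna2, Pclaf, Ube2c, Cx3cr1, Rrm2, Fads2, Birc5, Top2a, Mki67, Lmnb1 and Tk1, between -1.33 for Ccnb2 and -1.13 for Tk1. All of these act in division or DNA synthesis except Cx3cr1, the fractalkine receptor gene, at -1.24, the fatty acid desaturase gene Fads2 at -1.20, and the nuclear lamin gene Lmnb1 at -1.14. Of 21 cholesterol synthesis genes 19 fell, with a median of -0.49 (adjusted p = 2.16e-16, adjusted p = 0.123 with an estimated correlation), and 20 fell when adjusted over the list alone. Hmgcs1 went from 81.6 ± 9.26 to 55.3 ± 7.82 and Insig1, a sterol sensor, from 85.1 ± 10.4 to 58.3 ± 8.57.

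The genes that rose in R47H were led by Clec4n, from 10.7 ± 1.97 to 36.1 ± 6.49 FPKQ (log2 fold change 1.66, SE 0.11, limma adjusted p = 6.64e-09), and Thbs1, from 7.65 ± 1.84 to 24.9 ± 8.65. Ms4a4a, Slc40a1 and Cd4 rose by 1.41, 1.23 and 1.17, Apoe by 1.06, and Tmem176a and the monoglyceride lipase gene Mgll by 0.96 and 0.94. MHC class II genes took 4 of the 12 largest rises. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 rose by 1.15, 1.10, 1.04 and 1.01, and all 7 tested members of the list rose, with a median of 1.01 (adjusted p = 1.46e-05, adjusted p = 0.205 with an estimated correlation). Of 26 lysosomal genes 17 rose and 1 fell, with a median of 0.21 (adjusted p = 8.48e-07, adjusted p = 0.123 with an estimated correlation), and 18 rose and 1 fell adjusted over the list alone. Psap rose by 0.56 and Ctsb by 0.29. Under quantile normalization the change of Psap was 0.123 in both mutants, and its call was lost (limma adjusted p = 0.161). Equal values from unequal rises reflect ranks near the top of the scale, so this setting cannot size the change. The call of Ctsb was lost without a filter (limma adjusted p = 0.0823). The median of the list was 0.09 under quantile normalization and under equal sums. Macrophage identity genes rose in 12 and fell in 2 of 18 cases, with a median of 0.21 (adjusted p = 0.00209, adjusted p = 0.142 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.155). Adjusted over the list alone the counts of the MHC class II and macrophage identity lists were the same. The complement genes C1qa and C1qb rose by 0.75 and 0.54, and the integrin gene Itgam fell by 0.41. The call of Itgam was lost with a replicate block (limma adjusted p = 0.0591) and with depth as a covariate (limma adjusted p = 0.0710).

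Of 12 genes of alternative activation 6 rose and 1 fell, with a median of 0.34 (adjusted p = 0.0191, adjusted p = 0.193 with an estimated correlation), led by the lectin gene Clec10a at 0.89, and 7 rose and 1 fell adjusted over the list alone. Glycolysis genes fell in 5 of 20 cases and none rose, with a median of -0.10 (adjusted p = 0.00556, adjusted p = 0.427 with an estimated correlation), led by Aldoc at -0.45, and 6 fell and 1 rose adjusted over the list alone. Against WT Rep1 to Rep5 alone both calls were lost (adjusted p = 0.0738 and 0.270). Of 5 tested neutrophil genes 2 rose, Csf3r by 0.53 and Ngp by 0.54 (list adjusted p = 0.0301, adjusted p = 0.378 with an estimated correlation), as also adjusted over the list alone. This call was lost against WT Rep1 to Rep5 alone (adjusted p = 0.0738) and with the first residual component as a covariate (adjusted p = 0.0523). In KO 1 neutrophil gene rose (list adjusted p = 0.514). Neutrophil markers too low to be tested went both ways in KO, with Elane at 1.00 ± 0.470 in KO and 0.549 ± 0.566 in R47H against 0.374 ± 0.225 in wild type, Mpo at 1.10 ± 0.253 in KO and 0.822 ± 0.317 in R47H against 0.438 ± 0.165 in wild type and Prtn3 at 1.02 ± 0.305 in KO and 0.616 ± 0.167 in R47H against 0.398 ± 0.123 in wild type, but Camp at 0.255 ± 0.239 and 0.737 ± 0.490 in KO and R47H against 0.463 ± 0.174, Cxcr2 at 0.0999 ± 0.0740 and 0.111 ± 0.0719 against 0.148 ± 0.0617 and Retnlg at 0.0114 ± 0.0255 and 0.0256 ± 0.0351 against 0.164 ± 0.118. The calprotectin genes S100a8 and S100a9 stood at 24.7 ± 7.46 and 47.5 ± 17.1 in R47H against 17.9 ± 3.83 and 33.6 ± 8.29 in wild type and did not pass. Lists without a call in R47H included disease-associated microglia genes, with 10 of 23 that rose and 3 that fell (adjusted p = 0.0977), and LXR targets, with 4 of 16 that rose and 6 that fell (adjusted p = 0.484). Inflammatory genes, with 3 of 17 that rose (adjusted p = 0.334), immediate early and heat shock genes, with 2 of 16 that rose (adjusted p = 0.680), and Trem2 signalling genes, with 6 of 20 that rose and 2 that fell (adjusted p = 0.334), had none either. Adjusted over the list alone 11 microglia genes rose and 5 LXR targets rose and 7 fell, and the other counts were the same. The survival gene Mcl1 rose by 0.31 in R47H and did not pass in KO (limma adjusted p = 0.972), and R47H exceeded KO by 0.31 (adjusted p = 1.84e-05).

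In total 2301 genes passed in R47H against wild type, 1452 higher and 849 lower, and 341 passed with a change of at least 1.5-fold, 107 higher and 234 lower. Against WT Rep1 to Rep5 alone 1958 genes passed and against WT Rep6 to Rep10 alone 1955, of which 1082 passed against both in the same direction. Among the genes named for rank or as the target, the R47H libraries overlapped wild type for Trem2 and Mgll. The share of higher calls, 63.1%, was 48.6% under quantile normalization and 20.7% under equal sums, which moved the median of all genes by -0.11, so gene counts by direction depend on the scale. With depth, taken as the size of one fragment, as a covariate, an alternative chosen after seeing the data, 1126 genes passed. R47H Rep2 and Rep3 stood apart on the second principal component, and without them, also chosen after seeing the data, 1885 genes passed.

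Both mutants were set against each other across genes to ask how far their profiles coincide. Over 10843 genes the log2 fold changes of KO and R47H correlated with Pearson r = 0.727, a value across genes, which are not independent replicates. Since both share the wild-type libraries, unchanged groups were simulated against the same controls, and these gave a median r of 0.358 and a maximum of 0.772. The covariance was 0.0785, against a simulated median of 0.00430 and maximum of 0.0166. With KO against WT Rep1 to Rep5 and R47H against WT Rep6 to Rep10 the correlation was 0.716 and the covariance 0.0823, against a simulated maximum of 0.00947. With the sets exchanged they were 0.478 and 0.0575. Of the genes called in each comparison, 1000 rose in both where independent lists would share 410, and 730 fell in both where independent lists would share 201. Opposite calls numbered 36 that fell in KO and rose in R47H and 13 that rose in KO and fell in R47H. With the controls split in the first way, 875 rose in both and 713 fell in both, against 267 and 148 for independent lists, with 11 and 4 opposite calls. With the sets exchanged, 613 rose in both and 502 fell in both, against 332 and 157 for independent lists, and opposite calls numbered 177 that fell in KO and rose in R47H and 58 that rose in KO and fell in R47H.

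For genes that changed strongly in KO the R47H changes were mostly smaller and of the same sign. Among the 538 genes called in KO with a change of at least 1 on the log2 scale, 528 had the same sign in R47H, and the median R47H change was 43.8% of the KO change, with quartiles of 29.1% and 54.0%. These genes were selected by their size in KO, which lowers the share by chance. With the controls split in the first way the median was 50.9% and 532 had the same sign, and with the sets exchanged it was 35.6% and 501 had the same sign. By list, the R47H median was 54.4% of the KO median for G2 and M phase, 54.3% for S phase, 52.8% for cholesterol synthesis, 66.2% for lysosome and 70.5% for MHC class II. It was 51.7% for macrophage identity, 44.3% for alternative activation and 25.5% for glycolysis and hypoxia. The share for lysosome depends on the scaling, since the KO and R47H medians were 0.26 and 0.09 under quantile normalization. The share for MHC class II depends on the controls, since the KO and R47H medians were 1.21 and 1.23 with the controls split in the first way and 1.65 and 0.73 with the sets exchanged. Single genes also departed from the median share. Lpl, at -2.19 in KO, was -0.37 in R47H, and Ccnd1, at -3.05 in KO, was -0.60 in R47H, with -0.26 against WT Rep1 to Rep5 (adjusted p = 0.159) and -0.94 against WT Rep6 to Rep10. Tnf, which fell by 1.23 in KO, stood at 18.1 ± 3.91 in R47H against 16.8 ± 1.71 in wild type and did not pass (adjusted p = 0.558). Among the opposite calls, the stress response gene Ddit3 fell by 0.32 in KO and rose by 0.35 in R47H, and S1pr2, a receptor for sphingosine 1-phosphate, fell by 0.49 and rose by 0.13. These 2 were chosen after their values were seen, as genes whose R47H rise also passed against WT Rep6 to Rep10 alone.

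**Figure D2:**
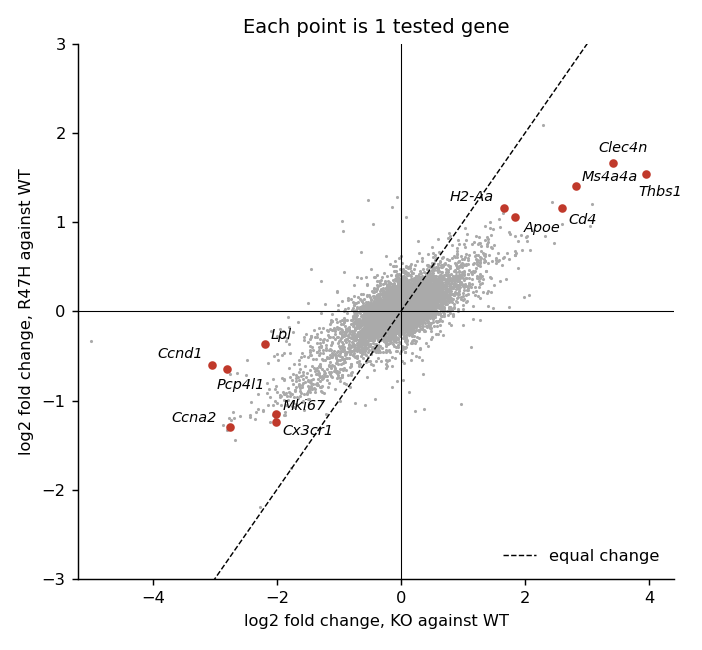
Log2 fold change of each tested gene in KO (horizontal axis) and in R47H (vertical axis), both against the 10 wild-type libraries, on the log2(FPKQ + 1) scale; the dashed line marks equal change. The named genes lie on the flatter side of that line, and r across the 10843 genes is 0.727.

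R47H was compared with KO directly to ask which transcripts differ between the mutants. The cell division genes were higher in R47H. All 22 G2 and M phase genes and 23 of 24 S phase genes rose, with medians of 0.96 and 0.55 (adjusted p = 8.00e-16 and 1.42e-13, both adjusted p = 0.165 with an estimated correlation). Apart from Trem2, the largest rises were those of Ccnd1 at 2.44, Pcp4l1 at 2.16, Slco4a1 at 1.95, the signalling regulator gene Rgs1 at 1.87 and Lpl at 1.82. The largest falls were those of Thbs1 at -2.40, F13a1 at -2.10, Mmp14 at -1.88, Ednrb at -1.87, Clec4n at -1.76 and Cmklr1 at -1.71, all genes that rose most in KO. Of 21 cholesterol synthesis genes 18 rose, with a median of 0.42 (adjusted p = 5.32e-07, adjusted p = 0.604 with an estimated correlation), and of 12 alternative activation genes 7 fell and 2 rose, with a median of -0.56 (adjusted p = 0.00415, adjusted p = 0.165 with an estimated correlation). Immediate early and heat shock genes rose in 8 of 16 cases and 1 fell (median 0.40, adjusted p = 0.0250), and inflammatory genes rose in 10 of 17 cases and 3 fell (median 0.35, adjusted p = 0.0496). Both were lost with an estimated correlation (adjusted p = 0.627 for each). Adjusted over the list alone, 10 and 11 of them rose and 1 and 3 fell, and the other counts were the same. The call of the inflammatory list was lost with a pseudocount of 0.1 (adjusted p = 0.0501) and that of the immediate early list with a minimum mean of 5 FPKQ (adjusted p = 0.0860). In all 4417 genes passed, 2470 higher and 1947 lower in R47H.

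The direct comparison carries any difference between the sets of wild-type littermates, so it was repeated as a difference of differences, an alternative chosen after seeing the data. The change of R47H from WT Rep6 to Rep10 was set against the change of KO from WT Rep1 to Rep5, chosen because, for genes that differ between the wild-type sets, KO lay nearer WT Rep1 to Rep5 than R47H did. Under it 1559 genes passed instead of 4417. All 12 genes of the previous ranking had the same sign, with Ccnd1 at 1.76, Lpl at 1.54, Thbs1 at -1.89 and Clec4n at -1.48. They were picked as the largest changes of the direct comparison, and both contrasts use the same mutant libraries. Their shared sign is therefore little evidence of its own. G2 and M phase and S phase genes still rose in 20 cases each (medians 0.95 and 0.54, adjusted p = 2.53e-18 and 9.60e-17, both adjusted p = 0.124 with an estimated correlation). MHC class II genes, called lower in R47H in the direct comparison (median -0.50, adjusted p = 0.0496, adjusted p = 0.627 with an estimated correlation), had 1 of 7 members called there, Ciita at -0.50, and 6 adjusted over the list alone. The list call was also lost with a pseudocount of 0.1 (adjusted p = 0.0518), and that of Ciita without R47H Rep2 and Rep3 (limma adjusted p = 0.223). In the difference of differences their median was 0.02 (adjusted p = 0.991), with Cd74 at 0.02 and H2-Aa at 0.04. Inflammatory genes and immediate early and heat shock genes were not called either (adjusted p = 0.348 and 0.866). Interferon response genes, not called in the direct comparison (adjusted p = 0.131), were called in this arrangement, with 6 of 24 higher in R47H and a median of 0.66 (adjusted p = 2.72e-04, adjusted p = 0.661 with an estimated correlation). Their KO and R47H medians against wild type were -0.45 and 0.22 in this arrangement and -0.05 and -0.13 with the sets exchanged, and the list was called lower in WT Rep6 to Rep10 than in WT Rep1 to Rep5 (median -0.27, adjusted p = 9.70e-04, adjusted p = 0.596 with an estimated correlation), so this call depends on the matching of the sets. The other way of matching the sets gave 4373 genes.

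**Figure D3:**
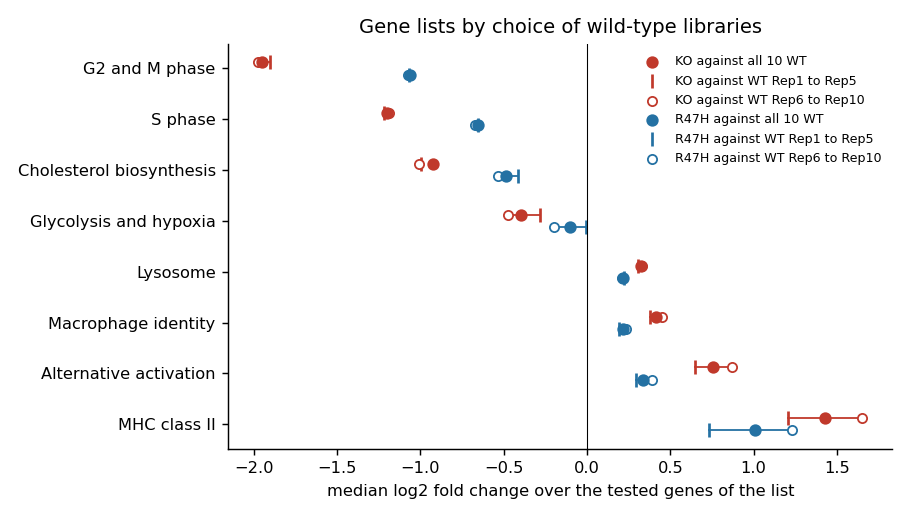
Median log2 fold change over the tested genes of 8 lists in KO (red) and R47H (blue), with filled points for all 10 wild-type libraries, ticks for WT Rep1 to Rep5 and open points for WT Rep6 to Rep10; lines join values of one mutant. The MHC class II medians depend most on the controls, from 1.21 to 1.65 in KO and from 0.73 to 1.23 in R47H.

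The wild-type libraries themselves differed by number. Between WT Rep1 to Rep5 and WT Rep6 to Rep10, 8 lists were called, 1 of them also with an estimated correlation, and 706 genes passed, 394 higher and 312 lower in the latter. Banp, which encodes a nuclear matrix protein, stood at 4.80 ± 0.531 FPKQ in WT Rep1 to Rep5 (SD, n = 5) and 9.18 ± 0.349 in WT Rep6 to Rep10 (n = 5), with 4.68 ± 0.345 in KO and 9.04 ± 0.686 in R47H. The chaperone gene Hsph1 stood at 9.98 ± 0.677 and 16.9 ± 1.59 in the wild-type sets, 10.3 ± 0.522 in KO and 15.5 ± 1.86 in R47H, and the cold-inducible gene Cirbp at 23.7 ± 2.56, 14.6 ± 1.10, 25.6 ± 5.21 and 16.6 ± 2.80 in the same order. Immediate early and heat shock genes were higher in WT Rep6 to Rep10, with 6 of 16 called, also over the list alone, and a median of 0.30 (adjusted p = 2.81e-07, adjusted p = 0.0465 with an estimated correlation), and the phosphatase gene Dusp1 went from 9.69 ± 0.668 to 26.9 ± 5.98. MHC class II genes were lower, with 2 of 7 called, 7 adjusted over the list alone, and a median of -0.44 (adjusted p = 9.51e-05, adjusted p = 0.358 with an estimated correlation). Banp, Hsph1, Cirbp and Dusp1 were chosen after their values were seen. On a first principal component that held 49.4% of the variance, KO libraries lay at 30.2 to 33.5, R47H at -4.22 to 4.17, WT Rep1 to Rep5 at -15.7 to -9.78 and WT Rep6 to Rep10 at -22.5 to -17.1.

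**Figure D4:**
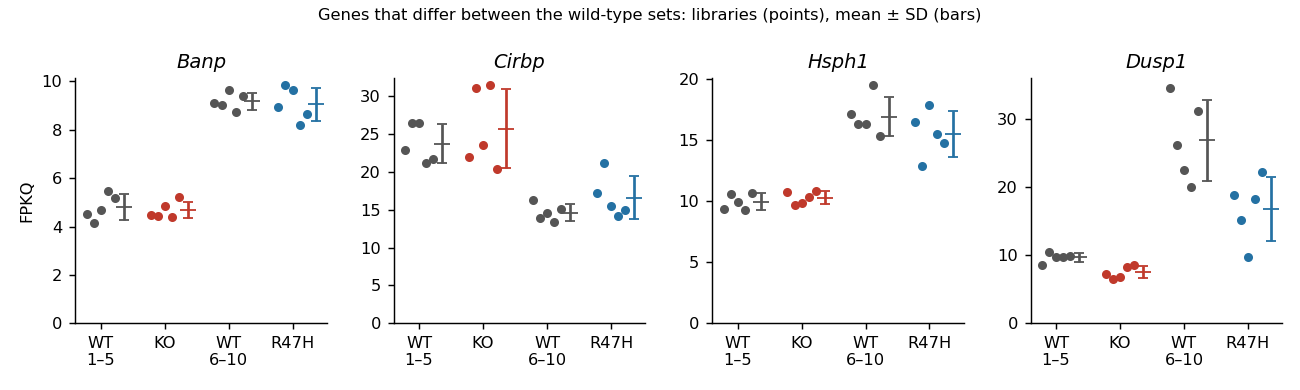
FPKQ of 4 genes that differ between the wild-type sets, in each library (points) with mean ± SD (bars, n = 5 each). For Banp, KO libraries lie with WT Rep1 to Rep5 near 4.80 and R47H libraries with WT Rep6 to Rep10 near 9.18.

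Markers of other cell types were mostly near 0. Cd3e, Flt3 and Zbtb46, markers of T cells and dendritic cells, had means of 0.00452 ± 0.00955, 0.152 ± 0.0795 and 0.0946 ± 0.0423 FPKQ in wild type (SD, n = 10), and no library exceeded 0.512 for any of these. In KO the mean of Cd3e was 0, and those of Flt3 and Zbtb46 were 0.302 ± 0.153 and 0.163 ± 0.0653 (n = 5). The other dendritic markers too low to be tested went both ways. Means were higher in KO for Cd209a, at 0.961 ± 0.178 against 0.346 ± 0.207 in wild type, and Dpp4, at 0.376 ± 0.0741 against 0.155 ± 0.0591, and lower for Clec9a, at 0.194 ± 0.104 against 0.273 ± 0.0984, Xcr1, at 0.0397 ± 0.0340 against 0.0523 ± 0.0203, and Bcl11a, at 0.130 ± 0.123 against 0.148 ± 0.0771. The lists of stroma and erythroid markers had no tested member. Of the stroma markers, Dcn stood at 0.719 ± 0.371 in KO against 0.106 ± 0.0583 in wild type, Sparc at 0.263 ± 0.130 against 0.0364 ± 0.0458, Col1a2 at 0.143 ± 0.0960 against 0.0227 ± 0.0208, and Col3a1 at 0.105 ± 0.0883 against 0.00516 ± 0.00511. Means were also higher in KO for Col1a1, Lum, Pdgfra, Pdgfrb, Cxcl12 and Lepr. Only Cdh5 had a lower mean, at 0.0685 ± 0.0245 against 0.0736 ± 0.0450. Whether the higher stroma markers share a source with the rises of Thbs1, Mmp14 and Vcam1 was not tested. No erythroid marker exceeded 0.539 in any library. Cd4 was the only tested lymphoid list member called in either mutant (list adjusted p = 0.319 in KO and 0.334 in R47H), while Il7r was present in all groups and did not pass (101 ± 12.5 in wild type, 98.6 ± 13.9 in KO, 104 ± 17.2 in R47H). Of 3 tested dendritic genes Kmo rose and Batf3 fell in KO (list adjusted p = 0.478), and 2 rose and 1 fell adjusted over the list alone. The call of Batf3 was lost against WT Rep1 to Rep5 alone and against WT Rep6 to Rep10 alone (limma adjusted p = 0.0615 and 0.183). It was also lost without any one of WT Rep2, Rep3, Rep5, Rep6, Rep8 or Rep10 or KO Rep1, Rep2, Rep3 or Rep5 (limma adjusted p up to 0.131). Of 7 tested osteoclast genes 4 rose and 1 fell in KO (adjusted p = 0.296), also adjusted over the list alone, and none passed in R47H (adjusted p = 0.614). The female transcript Xist exceeded 10 FPKQ in 4 of 10 wild-type, 4 of 5 KO and 4 of 5 R47H libraries, with 3 of those wild-type libraries in Rep1 to Rep5, so by this marker the mutant groups held a larger share of female animals. With the Xist level as a covariate 5249 genes passed for KO against wild type, instead of 5636. For R47H against wild type 1831 passed instead of 2301, and for R47H against KO 4378 instead of 4417.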

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

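The tests of a batch shared with the mutants and both tests of dendritic or lymphoid cells were chosen only after the result was seen, and the other tests in this part before it. Of 100 splits of the libraries for each comparison, 1, the real one, gave as many genes. That is the smallest share that 100 splits can give, so a chance split is argued against. The splits treat libraries as exchangeable, so they cannot tell genotype from a batch shared within a group. The real counts were 5636, 2301, 4417 and 706 for KO against wild type, R47H against wild type, R47H against KO and the wild-type sets, and the highest among the other splits were 3679, 662, 1957 and 0.

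R47H libraries moved in the direction of KO with smaller changes. Shared wild-type controls are argued against as the source, since with the controls split the covariance of the fold changes was 0.0823, above the highest of 100 simulated values, 0.00947. The slope of R47H on KO fold changes over genes called in KO was 0.358 with the Trem2 level as a covariate and 0.370 without it. With that covariate it was at least 0.318 without any one R47H library. With depth as the covariate it was 0.333, and at least 0.316 without any one R47H library. Differences of Trem2 or depth within groups thus did not account for the pattern. Neither test can settle whether lower Trem2 mRNA or fewer fragments per FPKQ contribute, since the covariates draw only on those differences. A partial loss of Trem2 function through the substitution may underlie the pattern, a hypothesis that these data cannot separate from a litter or culture batch, which the labels do not give.

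WT Rep1 to Rep5 and WT Rep6 to Rep10 differed in 706 genes. With the Xist level as a covariate 711 genes passed and with depth 598, so sex ratio and depth are argued against as the source of most of the difference. On an axis from WT Rep1 to Rep5 (0) to WT Rep6 to Rep10 (1) the median position over these genes was -0.365 for KO and 0.469 for R47H, a gap of 0.834. A batch or litter shared by KO with the first set and by R47H with the second is a candidate explanation, and the order of the sample list goes with it. R47H lay about midway, however, and genotype moves the same genes, so batch and genotype cannot be told apart for them. Of biological explanations only the sex ratio was tested.

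MHC class II genes and Cd4 were higher in both mutants. The first test asked whether any other dendritic or lymphoid marker reached 5% of the H2-Ab1 level in KO, 17.3 FPKQ. Il7r did, at 98.6, but stood at 101 in wild type, so that test left the question open, and the next test, on the rise from wild type, was set after that was seen. In it the largest rise among 22 other markers was that of Kmo, 2.10 FPKQ, under the bound of 11.6. That bound rests on an assumed share, and for 2 of the 22, Kmo and Dpp4, every KO library lay above every wild-type library, so the test leaves such cells open. Chance gives such a separation in 0.0333% of unchanged genes. Its share over all genes is not given here, and 3063 of 10843 tested genes were called higher in KO. More female animals are argued against, since the MHC class II median in KO was 1.37 with the Xist level as a covariate and 1.43 without, so dendritic or lymphoid cells, differences of litter and a change within macrophages stay open.

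For the 127 genes named, 381 groups were tested for a library far from the others, and 19 held one, where chance gives about 1 in 20. Xist, which males do not express, stood at 0.0105 FPKQ in KO Rep1 and 0.0146 in R47H Rep5, with the other libraries of each group at 30.1 or more. Col1a2 was high in KO Rep4 at 0.31 and Sparc low in KO Rep1 at 0.0353, Cdh5 was high in WT Rep3 at 0.1848 and Clec9a low in R47H Rep1 at 0.1249, and Retnlg stood at 0.0571 in KO Rep2 and 0 in the other KO libraries. KO Rep3 was low for Cyp51 at 14.5 and Lmnb1 at 2.30, and KO Rep5 was low for C1qb at 1950.0 and Ndufb8 at 68.9. WT Rep7 was low for C1qa at 206 and Ndufb8 at 76.9, and Frs3 was high in KO Rep4 at 2.07. R47H Rep4 was high for Ednrb at 5.53 and Mgl2 at 10.8 and low for S100a8 at 12.5. R47H Rep3 was low for Mertk at 21.4 and high for Atp5b at 360.2.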

How the results depend on the processing

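The difference of differences, depth as a covariate, the fit without R47H Rep2 and Rep3 and the unblocked fit of the block's libraries were chosen after seeing the data. Over the alternatives, 137 of 152 gene and list counts stayed within 1.5 times their value, 8313 of 8537 fold changes of named genes and 270 of 311 list results kept their direction and side of the threshold, and 223 gene and 41 list results kept their direction but lost their call. A change of at least 1.5-fold left 1320, 341 and 726 genes for KO against wild type, R47H against wild type and R47H against KO, a stricter criterion by construction. An estimated correlation left 0, 2 and 0 lists, since it widens the list test, and no filter on low values gave 13 lists for R47H against KO (the cause was not tested). Depth as a covariate gave 1126 genes for R47H against wild type (the cause was not tested). The size of one fragment, which served as that covariate, was 0.0377 ± 0.00260 FPKQ times kb in R47H (SD, n = 5) and 0.0326 ± 0.00258 in wild type (n = 10). It therefore overlaps with genotype, and it moves with the FPKQ scale as well as with depth. The difference of differences gave 1559 genes for R47H against KO with one matching of the wild-type sets and 4373 with the other. Trem2 in R47H against WT Rep6 to Rep10 was -0.27 (exact p = 0.135), and the correlation of the mutants with the wild-type sets exchanged was 0.478 (the cause was not tested). Atp5b, -0.10 in KO, was 0.0011 under quantile normalization (adjusted p = 0.985; the cause was not tested), and its call in KO was also lost without most single libraries, the highest adjusted p being 0.110 without KO Rep1.

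Pairing by replicate number was checked among KO, R47H and WT Rep1 to Rep5, so a pairing with WT Rep6 to Rep10 was not tested. Same-numbered libraries correlated at -0.254 to 0.341 for KO with wild type, 0.0223 to 0.224 for R47H with wild type and -0.120 to 0.309 for KO with R47H. A number correlated best with its own in 1, 2 and 1 of 5 pairs, so these numbers did not pair the libraries checked. The replicate block also left out WT Rep6 to Rep10. With it 5012, 1313 and 3048 genes passed for KO and R47H against wild type and R47H against KO. The same libraries without the block gave 5379, 1678 and 3520.

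Leaving out each library in turn gave 5217 to 5607 genes for KO against wild type, 1704 to 2312 for R47H against wild type and 3743 to 4709 for R47H against KO. It gave -5.03 to -4.99 for Trem2 in KO and -0.40 to -0.24 in R47H, where the highest exact p was 0.04995. Between the wild-type sets it gave 417 to 617 genes, with 417 without WT Rep3, 421 without Rep4, 466 without Rep5, 451 without Rep6 and 457 without Rep10, against 706 (the cause was not tested). Without R47H Rep2 and Rep3 1885 genes passed for R47H against wild type, 1390 of them shared with the 2301 in direction, and 3230 for R47H against KO. FPKQ 1 in a 2 kb gene rested on 52.4 and 53.3 fragments in KO and R47H against 61.7 in wild type, which limits the genes near the minimum level most.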

Other observations

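The lists of stress response, survival and migration genes were not called in either mutant. Of 17 genes of the integrated stress response 5 rose and 11 fell in KO (list adjusted p = 0.102), and 3 rose and 6 fell in R47H (adjusted p = 0.0823). Mthfd2, Psat1 and Phgdh, which act in serine and one-carbon metabolism, fell by 1.17, 1.15 and 1.58 in KO and by 0.53, 0.57 and 0.80 in R47H. The amino acid transporter gene Slc3a2 rose by 0.63 and 0.34. Of 20 survival genes 5 rose and 7 fell in KO (adjusted p = 0.251), and 4 rose and 4 fell in R47H (adjusted p = 0.740). Bcl2l1, Ccnd2 and Myc fell by 1.11, 1.01 and 1.88 in KO. Of 13 migration receptors 5 rose and 5 fell in KO (adjusted p = 0.858), and 2 rose and 3 fell in R47H (adjusted p = 0.686). Cx3cr1 fell by 2.02 in KO, and the chemokine receptor gene Ccr2 fell by 0.68 in R47H. Adjusted over the list alone, 3 stress response genes rose and 7 fell in R47H, 6 survival genes rose and 6 fell, and 2 migration genes rose and 4 fell, and the KO counts of these lists were the same.

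Phagocytosis receptors rose in 9 and fell in 6 of 18 cases in KO (adjusted p = 0.248) and rose in 7 and fell in 2 in R47H (adjusted p = 0.0581), with the same counts adjusted over the list alone. Fcgr2b, Mertk and Fcgr3 rose by 2.33, 1.84 and 0.62 in KO and by 0.85, 0.84 and 0.33 in R47H. Of 24 interferon response genes 6 fell and 1 rose in KO (adjusted p = 0.172), among them Oas1a and Oasl2, which fell by 0.43 and 0.68, and 4 fell and none rose adjusted over the list alone. With depth as a covariate Oas1a and Oasl2 stood at -0.24 and -0.47 in KO and their calls were lost (limma adjusted p = 0.154 and 0.124). None of the 24 passed in R47H (adjusted p = 0.950). Of 20 genes of oxidative phosphorylation 3 fell and 1 rose in KO (adjusted p = 0.599), of which none fell and 1 rose adjusted over the list alone, and 2 rose in R47H, Ndufs3 by 0.45 and Ndufb8 by 0.40 (list adjusted p = 0.334). The call of Ndufb8 was lost without R47H Rep2 or without R47H Rep3 (limma adjusted p = 0.0647 and 0.0753). The mast cell and basophil list had 1 tested gene, Kit, which fell by 0.40 in KO (list adjusted p = 0.427), a call lost against WT Rep6 to Rep10 alone (limma adjusted p = 0.0577), and was not called in R47H (list adjusted p = 0.348), except when adjusted over the list alone, where it fell. None of the 5 sex-linked genes passed in either mutant (list adjusted p = 0.599 in KO and 0.334 in R47H).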
